A study of Homo sapiens with 6 samples.

How the data were processed

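Poly(A) RNA from A549, a human lung adenocarcinoma cell line, was compared between 3 libraries labelled as STAU1 knockdown and 3 control libraries. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, mRNA was captured on beads, directional libraries were made, and paired-end reads of 150 nt were sequenced on an Illumina instrument. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels call the control samples plasmid controls while the knockdown columns carry the prefix si. The sequence of the knockdown reagent is not given in the sources used here.

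The authors deposited a table of read counts per gene, with 1 column per library and whole-number values. The authors also deposited FPKM values (fragments scaled by gene length in kilobases and by library depth), rounded to 2 decimals, for the same libraries. Per the submitters' processing notes, HISAT2, DESeq2 and the GRCh38 build were used, with no role or version stated. The counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner may therefore not be separated, and genes with near-identical copies may share reads. The deposited FPKM divisor per library was not the count total: relative to control replicate 1, the divisor of knockdown replicate 3 was 1.05 and its count total was 1.11. Gene identifiers were matched to GENCODE 29 for chromosome, coordinates, transcript sequence and gene type. Of 30493 listed identifiers, 29556 matched (96.9%), and unmatched genes stayed in the test without these annotations.

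Columns were assigned to libraries by their names, which equal the sample titles. The total count was 31791407, 31458569 and 32832268 in control replicates 1 to 3 and 30354219, 31033209 and 35431441 in knockdown replicates 1 to 3. No pair of replicates differed as little as sampling noise, with a chi-square per degree of freedom between 1.78 and 2.88 over the genes with at least 10 counts in a pair, so every library was counted on its own. This does not show that the libraries came from separate cultures. The common dispersion fitted by edgeR corresponded to a coefficient of variation of only 2.61% between libraries of a group. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17089 genes. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. CPM values in the text are TMM-scaled, errors of CPM are SDs over 3 libraries, and errors of log2 fold changes are standard errors, taken as the size of the log2 fold change over the square root of its F statistic. Log2 fold changes are the values fitted by edgeR, knockdown minus control, and the log2 CPM values given to camera used a prior count of 2.

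A total of 37 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. The rule named STAU1 and its paralog STAU2, the 5 genes with the largest rises and the 5 with the largest falls among called genes with a mean log2 CPM of at least 3 and non-overlapping groups, and, for the 6 lists with the smallest camera p, the 3 members with the smallest adjusted p. Lists of other-cell markers, mitochondrially encoded mRNAs and histones were described apart from these 6. All other genes named in the text were chosen after their values were seen, and some list members are not reported here.

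Alternatives were RLE size factors, upper-quartile and total-count scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, edgeR's legacy quasi-likelihood test, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), loess offsets (span 0.3) for gene length and transcript GC content, the replicate number as a block, both offsets with the block, and each library left out in turn. The script was tested on simulated counts for the 17089 genes, with 50 genes changed at each size. The quasi-likelihood test recovered 64% of genes changed by a log2 of 0.25, 68% at 0.5, 90% at 1 and 96% at 2, with 15 false calls among 16889 unchanged genes. In the data 44.1% of genes were called, far more than were changed in the simulation, so these rates need not hold there.

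For sequence patterns, 3' UTRs of at least 50 nt were taken from GENCODE 29 for 11612 protein-coding genes other than STAU1 with a mean log2 CPM of at least 1. Each gene was given its protein-coding transcript with the longest annotated 3' UTR. A site or Alu there need not lie in the 3' UTR that A549 cells express. Log2 fold changes beyond 1 in either direction were set to 1 or -1 so that single genes did not decide a mean. All 15887 7-mers present in at least 100 of these genes were compared by mean log2 fold change after adjustment for 3' UTR length, GC content and expression, and the range of z was set against 100 permutations. Alu elements in 3' UTRs were matches of at least 100 nt to an Alu consensus, found with blastn 2.17.0 at an E-value of at most 1e-10. The consensus was written from general knowledge and not taken from a repeat database. The models used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Intervals of counts and shares are exact, cover counting error only and have a level of 95%. A fold against a group with no counts was computed against a floor of 3 counts over the group. Alternative splicing, which the series title names, needs exon-level data and was not analysed here.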

Results

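The data set held 6 RNA-seq libraries of A549 cells, 3 controls and 3 with knockdown of STAU1, which encodes a double-stranded RNA-binding protein known for mRNA transport, translation and Staufen-mediated mRNA decay. The comparison asked which transcripts differ in amount when STAU1 is depleted. Libraries held between 30354219 and 35431441 counts, and 17089 of 30493 listed genes had enough counts to be tested. The mitochondrially encoded genes took 17.3%, 17.4% and 17.9% of the counts in control replicates 1 to 3 and 15.8%, 16.1% and 16.1% in knockdown replicates 1 to 3.

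STAU1 (ENSG00000124214.21, chromosome 20, 49113339 to 49188367, minus strand, GRCh38 coordinates of GENCODE 29) fell 7.83-fold, from 121 ± 3.71 CPM in controls to 15.4 ± 0.732 CPM in knockdown libraries (SD, n = 3 each). The knockdown libraries held 16.02, 15.7 and 14.6 CPM and the controls 120, 125 and 117. Cell cycle, ribosomal protein, respiratory chain and glycolysis transcripts fell, by modest amounts, while p53 targets, mesenchymal genes and ER chaperones rose. These list calls are from camera with its preset correlation, and 0 of the 37 lists passed with an estimated correlation, where the lowest adjusted p was 0.155. The smooth muscle actin gene ACTA2 rose 2.86-fold (log2 fold change 1.52, SE 0.08) and the collagen gene COL1A1 rose 2.81-fold (1.49, SE 0.09). STC2, which encodes a secreted glycoprotein, fell by 1.34 on the log2 scale (SE 0.07). The STAU1 paralog STAU2 rose from 35.3 ± 0.567 to 41.3 ± 0.921 CPM (log2 fold change 0.23, SE 0.04), with an adjusted p of 1.9e-05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 1.9e-34 for STAU1.

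**Figure D1:**
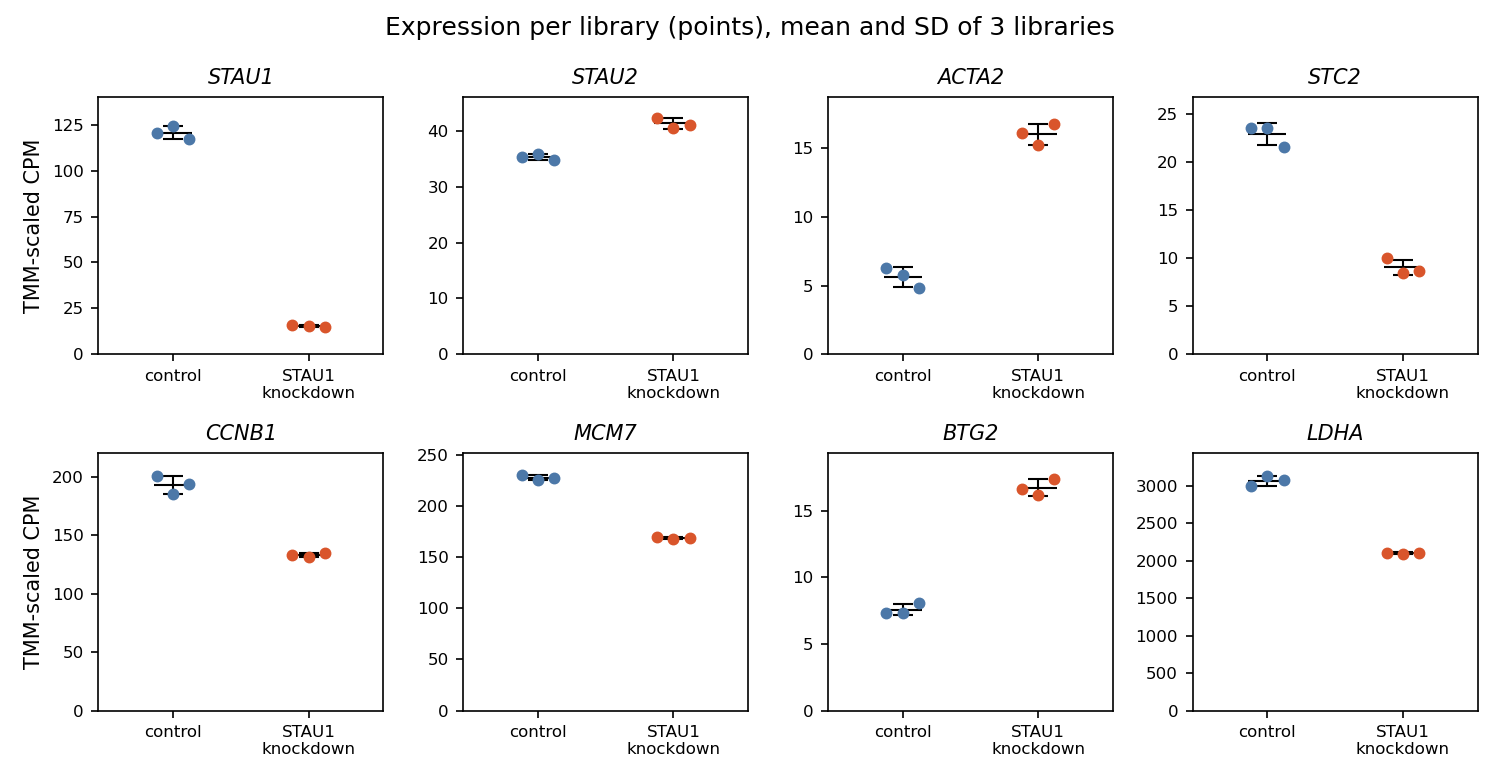
TMM-scaled CPM of 8 genes in each library, with points for the 3 control (blue) and 3 knockdown (orange) libraries and black bars for the mean and SD. STAU1 lay between 117 and 125 CPM in controls and between 14.6 and 16.02 CPM in knockdown libraries, and the groups did not overlap for STAU2, ACTA2, STC2, CCNB1, MCM7, BTG2 or LDHA.

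In all, 3790 genes were higher and 3741 lower in knockdown libraries at an adjusted p under 0.05, which is 44.1% of the tested genes. Most changes were small. The median fold was 1.23 among the higher and 1.18 among the lower genes, and 189 genes were at least 2-fold higher and 91 at least 2-fold lower. These 2-fold counts depended on the setting, with 287 and 168 with no filter on low counts, 102 and 28 with the CPM filter, 14 and 3 with log2(FPKM + 1) and 88 and 20 with log2(FPKM + 0.1). DESeq2 gave 59 at least 2-fold lower, and without knockdown replicate 1 there were 150. Of the calls 50.3% were higher, against 69.5% with total-count scaling, 77.3% with log2(FPKM + 1) and 77.2% with log2(FPKM + 0.1). Groups did not overlap for 8780 genes (51.4%), where chance gives 10%. Protein-coding genes made up 3500 of the higher and 3428 of the lower calls, and lncRNAs 243 and 241.

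The 5 largest rises among genes of at least moderate expression were ACTA2, COL1A1, KCNJ16, DCDC1 and MAPK4. KCNJ16, an inward-rectifier potassium channel gene, rose from 5.99 ± 0.702 to 16.6 ± 1.00 CPM (log2 fold change 1.47, SE 0.08). DCDC1, a doublecortin-domain gene, rose from 12.7 to 32.8 CPM (1.37, SE 0.06) and MAPK4, an atypical MAP kinase gene, from 5.26 to 13.6 CPM (1.37, SE 0.08). ACTA2 may share reads with other actin genes, so its level is uncertain. After STAU1, the largest falls were STC2, MASTL, AKR1B1 and NFKB2. STC2 went from 22.9 ± 1.15 to 9.03 ± 0.825 CPM. MASTL, the Greatwall kinase that acts at mitotic entry, fell from 35.1 to 16.5 CPM (-1.09, SE 0.05). AKR1B1, the aldose reductase gene, was among the abundant transcripts and fell from 3928 to 1974 CPM (-0.99, SE 0.06, adjusted p = 1.9e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NFKB2, which encodes the p100 precursor of an NF-kB subunit, fell from 33.7 to 17.2 CPM (-0.97, SE 0.05).

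**Figure D2:**
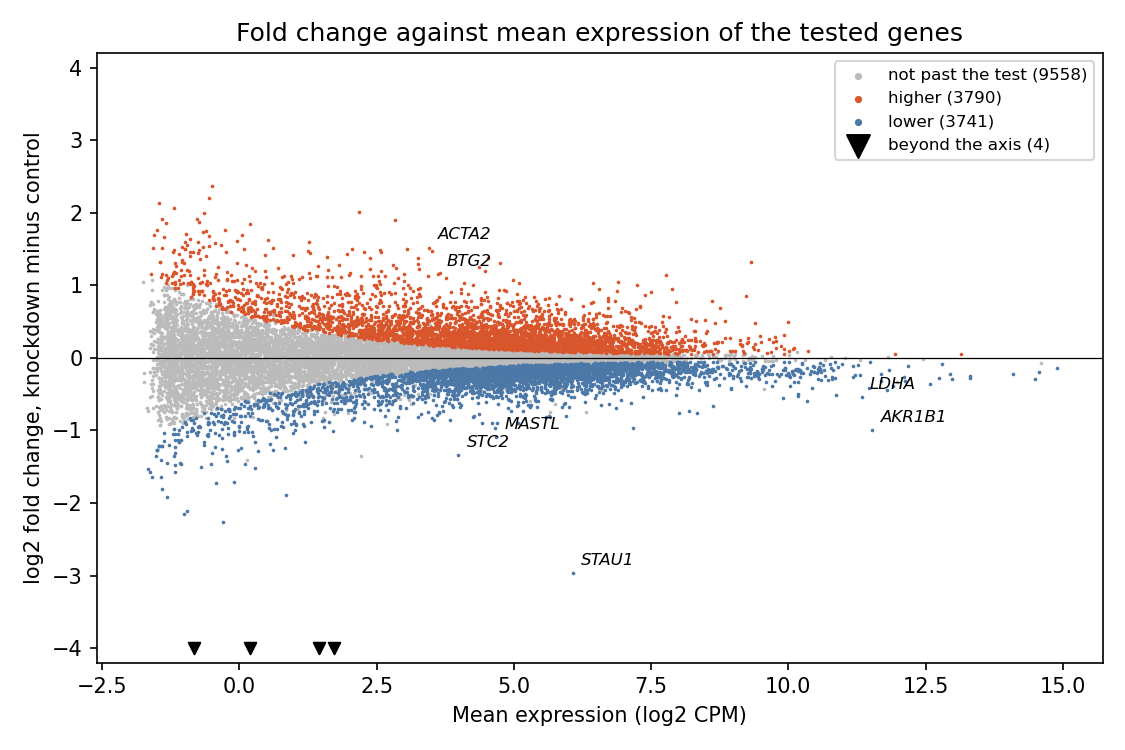
Log2 fold change (knockdown minus control) of each tested gene against its mean log2 CPM, with 3790 genes higher (orange), 3741 lower (blue) and the rest not past the test (grey). Most called genes lay near 0, STAU1 lay at -2.97, and the black triangles mark SFTPA1, SFTPA2, SFTPB and SLC34A2, whose fitted values lay beyond the axis.

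Cell cycle genes fell as a group. In the list of G2/M and mitosis genes 41 of 44 tested members fell, 0 rose and 3 were not called, with a median log2 fold change of -0.31, but -0.18 with log2(FPKM + 1) and -0.20 with log2(FPKM + 0.1) (camera's adjusted p = 1.1e-13, and adjusted p = 0.155 with an estimated correlation). CCNB1, the mitotic cyclin, went from 193 ± 7.57 to 133 ± 1.60 CPM (-0.54, SE 0.03), and the anaphase activator CDC20 changed by -0.61 (SE 0.03). PTTG1, the securin gene, changed by -0.55, though near-identical copies may share its reads. The G1/S and DNA replication list had the same counts, 41 of 44 lower and 3 not called, with a median of -0.31, but -0.17 with log2(FPKM + 1) and -0.20 with log2(FPKM + 0.1) (camera's adjusted p = 1.1e-13, and adjusted p = 0.155 with an estimated correlation). Its leading members were the replicative helicase subunits MCM7 (228 to 169 CPM, -0.43, SE 0.02) and MCM5 (-0.55, SE 0.03) and the cyclin gene CCND1 (-0.51, SE 0.03). Among 34 p53 targets 26 rose, 4 fell and 4 were not called (median 0.24, camera's adjusted p = 2.5e-05, and adjusted p = 0.155 with an estimated correlation). BTG2, an antiproliferative gene, rose from 7.56 to 16.7 CPM (1.15, SE 0.07), the p53 ubiquitin ligase gene MDM2 from 72.5 to 101 CPM (0.48, SE 0.03) and the ribosomal protein-like gene RPS27L by 0.34 on the log2 scale (SE 0.02). CDKN1A, the p21 cell cycle inhibitor gene, rose by 0.16.

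Transcripts of protein synthesis and respiration were lower. Of the 76 cytosolic ribosomal protein genes 70 fell, 0 rose and 6 were not called (median -0.18, but -0.10 with total-count scaling and -0.07 on either FPKM scale, camera's adjusted p = 5.7e-16, and adjusted p = 0.286 with an estimated correlation). RPL37 went from 946 ± 8.48 to 724 ± 12.7 CPM (-0.39, SE 0.02), RPL35 changed by -0.41 and RPS15 by -0.38, and all 3 have processed pseudogenes that may share reads. In the ribosome biogenesis and MYC target list 23 of 31 fell, 3 rose and 5 were not called (median -0.17, camera's adjusted p = 2.6e-05, and adjusted p = 0.155 with an estimated correlation). The nuclear-encoded respiratory chain list had 39 of 49 members lower, 3 higher and 7 not called (median -0.18, but -0.10 with total-count scaling and -0.07 on either FPKM scale, camera's adjusted p = 7.2e-08, and adjusted p = 0.166 with an estimated correlation). Among them were the cytochrome c1 gene CYC1 (-0.35, SE 0.03) and the ATP synthase genes ATP5MC1 (-0.35, SE 0.03) and ATP5F1B (-0.22, SE 0.02). Of 13 mitochondrially encoded mRNAs 12 fell and 1 was not called (median -0.27, camera's adjusted p = 5.4e-06, and adjusted p = 0.155 with an estimated correlation), including MT-CYB at -0.29 and MT-ND4 at -0.29. Of 37 hypoxia and glycolysis genes 23 fell, 5 rose and 9 were not called (median -0.29, camera's adjusted p = 2.5e-05, and adjusted p = 0.155 with an estimated correlation). The lactate dehydrogenase gene LDHA went from 3065 ± 68.4 to 2099 ± 13.4 CPM (-0.55, SE 0.02), and the glycolytic genes PGK1 and ENO1, which also have pseudogenes, changed by -0.52 and -0.42. Of the genes named by the rule, LDHA, RPL37 and STAU2 hold the 7-mer TTAGTCA or TAGTCAA in their longest annotated 3' UTR. LDHA, RPL37, PGK1, MDM2, RPS27L and DCDC1 hold an Alu element there, though A549 cells may express a shorter 3' UTR. In coding sequence, apart from STAU1, MASTL and MDM2 hold such a 7-mer and KCNJ16 holds the 8-mer TTAGTCAA. MASTL fell, and MDM2 and KCNJ16 rose.

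**Figure D3:**
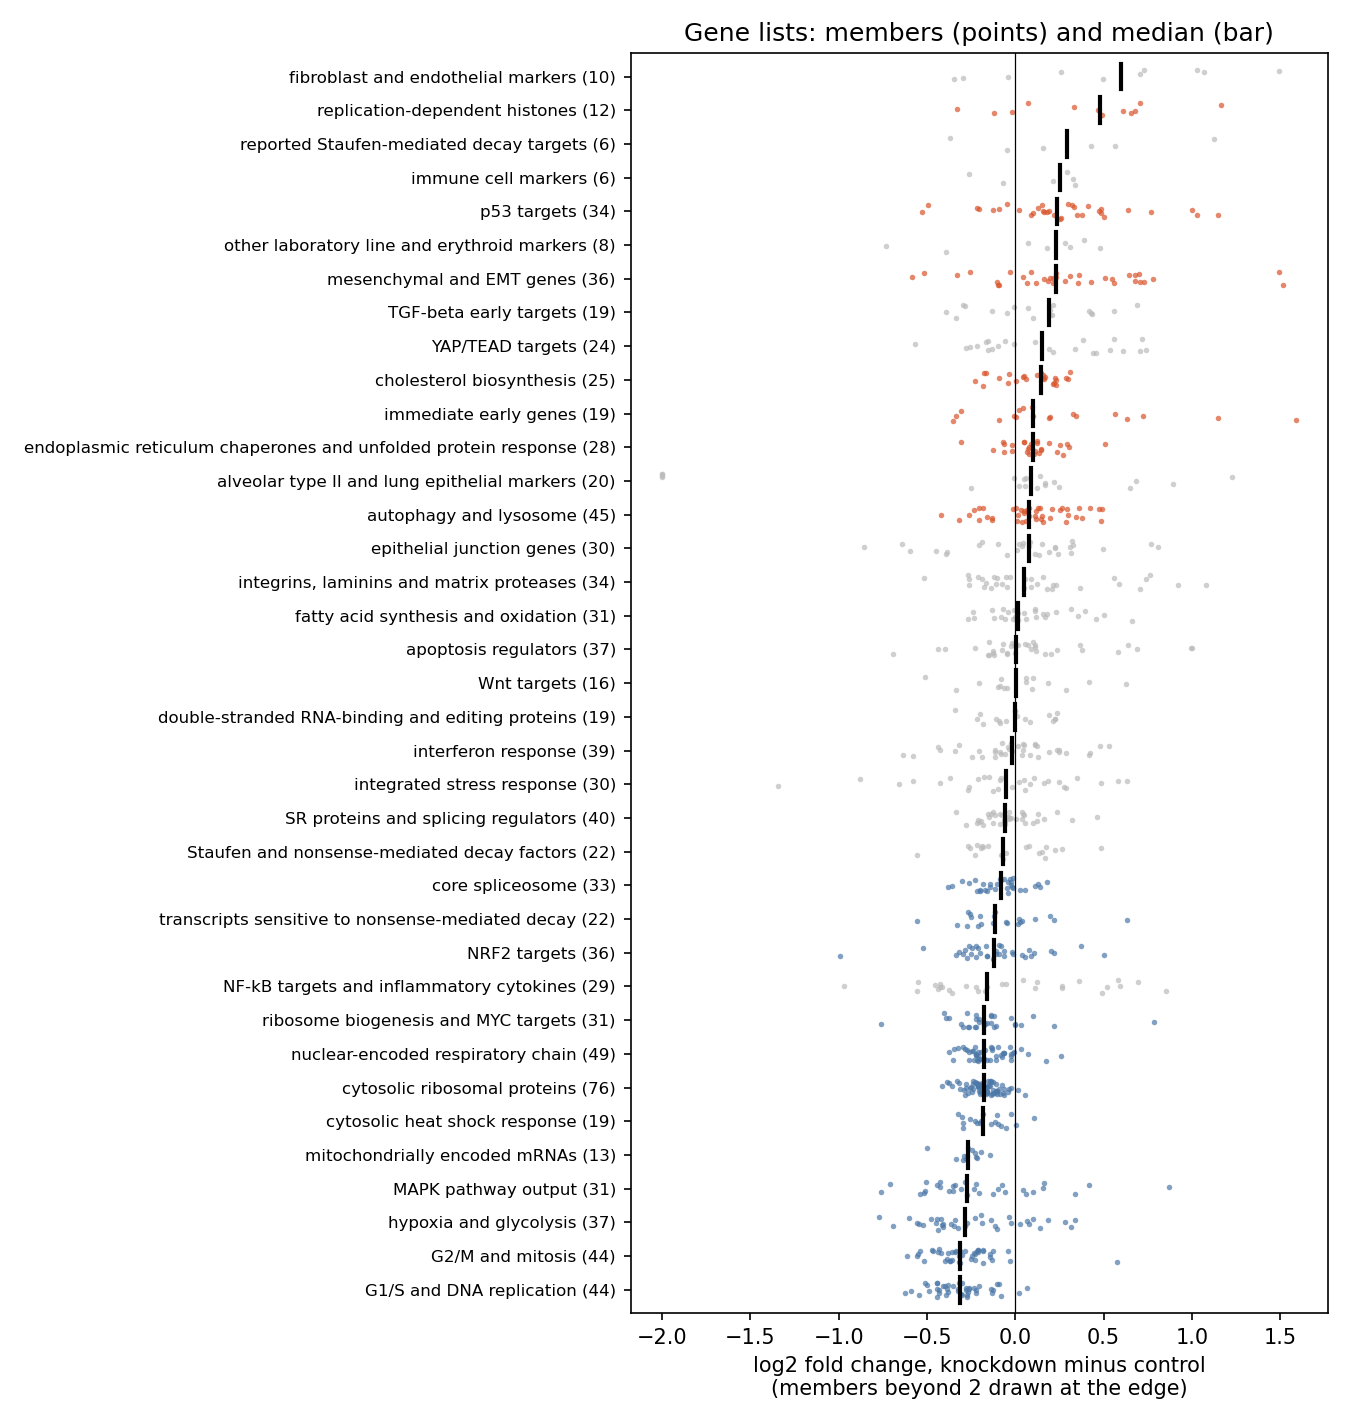
Log2 fold change (knockdown minus control) of the tested members of 37 gene lists as points, with a black bar at each median and the number of tested members in brackets; colour marks lists past camera with its preset correlation, 7 higher (orange) and 12 lower (blue), and the others are grey. The 2 cell cycle lists had medians of -0.31, core spliceosome had -0.08 but 0.03 with either FPKM scale, and histones had 0.48 but -0.01 with no filter on low counts.

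Among stress and signalling lists, 15 of 19 heat shock response genes fell, 1 rose and 3 were not called (median -0.18, camera's adjusted p = 7.5e-05, and adjusted p = 0.155 with an estimated correlation). The cytosolic co-chaperone gene STIP1 changed by -0.30. The list also holds mitochondrial chaperonin genes, of which HSPE1 changed by -0.33 and HSPD1 rose by 0.11. Of 31 MAPK pathway output genes 19 fell, 4 rose and 8 were not called (median -0.27, camera's adjusted p = 6.0e-04, and adjusted p = 0.155 with an estimated correlation), with the ephrin receptor genes EPHA2 at -0.54 and EPHA4 at 0.87. Of 36 NRF2 targets 25 fell, 6 rose and 5 were not called (median -0.12, camera's adjusted p = 0.0011, and adjusted p = 0.346 with an estimated correlation). The heme oxygenase gene HMOX1 was among those higher, at 0.50, and the aldo-keto reductase gene AKR1C3 among those lower, at -0.32. The ER chaperone and unfolded protein response list had 17 of 28 higher, 2 lower and 9 not called (median 0.10, camera's adjusted p = 0.0065, and adjusted p = 0.346 with an estimated correlation), with the chaperone genes CALR at 0.25 and PDIA3 at 0.27. Of 25 cholesterol biosynthesis genes 14 rose, 4 fell and 7 were not called (median 0.15, camera's adjusted p = 0.0117, and adjusted p = 0.155 with an estimated correlation), with the lanosterol synthase gene LSS at 0.31 and the sterol sensor gene INSIG1 at -0.18, a call lost on both FPKM scales. Of 45 autophagy and lysosome genes 22 rose, 8 fell and 15 were not called (median 0.08, camera's adjusted p = 0.0140, and adjusted p = 0.224 with an estimated correlation), a call lost with DESeq2 (adjusted p = 0.0588) and with the length offset and replicate block (adjusted p = 0.0515). Among 19 immediate early genes 10 rose, 2 fell and 7 were not called (median 0.10, camera's adjusted p = 0.0221, and adjusted p = 0.155 with an estimated correlation), with the nuclear receptor gene NR4A3 at 1.59 and KLF6 at 0.73.

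Mesenchymal and EMT genes were higher, with 19 of 36 up, 3 down and 14 not called (median 0.23, camera's adjusted p = 3.1e-05, and adjusted p = 0.155 with an estimated correlation). The cadherin gene CDH2 rose by 0.65, the growth factor gene TGFB2 by 0.71 and the fibronectin gene FN1 by 0.31. The lysyl oxidase gene LOXL2 fell by 0.59. Of 25 replication-dependent histone genes only 12 had enough counts to be tested, with a median control level of 4.29 CPM. Among these 12 genes 8 rose and 4 were not called (median 0.48, though -0.01 with no filter on low counts, camera's adjusted p = 0.0027, and adjusted p = 0.166 with an estimated correlation). The libraries were made from poly(A) RNA, so these values cover only histone transcripts that this capture recovered and need not show total histone mRNA. H2BC5 rose by 1.17 and H2BC12 by 0.66. Of 10 fibroblast and endothelial markers 5 were higher, 2 lower and 3 not called (camera's adjusted p = 0.0984, and adjusted p = 0.260 with an estimated correlation), with the proteoglycan gene LUM at 0.71 and the vascular cadherin gene CDH5 at 1.03. Of 6 immune cell markers 1, the monocyte gene CD14 at 0.33, was higher and 5 were not called (camera's adjusted p = 0.344). Among 8 markers of other laboratory lines and erythroid cells 1 was higher, 2 lower and 5 not called (camera's adjusted p = 0.553).

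RNA decay and splicing lists were of interest because of the known functions of STAU1. Of 6 reported Staufen-mediated decay targets 4 were higher, 1 lower and 1 not called (camera's adjusted p = 0.0958, and adjusted p = 0.346 with an estimated correlation). The transcription factor gene KLF2 rose by 1.12 and JUN by 0.56. SOWAHC fell by 0.37, a call lost on both FPKM scales, and the ADP-ribosylation factor gene ARF1 had -0.05. Of 22 transcripts sensitive to nonsense-mediated decay 12 fell, 3 rose and 7 were not called (median -0.12, camera's adjusted p = 0.0455, and adjusted p = 0.166 with an estimated correlation). That call ended without control replicate 1 or 2 and without knockdown replicate 1 or 3, with adjusted p of 0.0572, 0.0762, 0.0533 and 0.0575 from camera. It also ended with total-count scaling (median -0.04, adjusted p = 0.108 from camera), the CPM filter (0.0586), both FPKM scales (medians -0.0057 and -0.0058, adjusted p = 0.218 and 0.215), the replicate block (0.0776) and the length offset with the block (0.0516). Of 22 Staufen and nonsense-mediated decay factors 7 rose, 9 fell and 6 were not called (camera's adjusted p = 0.406), with the helicase gene UPF1 at -0.25, SMG5 at -0.56 and the decapping gene DCP2 at 0.48. Core spliceosome genes had 17 of 33 lower, 3 higher and 13 not called (median -0.08, but 0.03 with either FPKM scale and -0.0023 with total-count scaling, all 3 no longer past camera, camera's adjusted p = 0.0027, and adjusted p = 0.155 with an estimated correlation), including SNRPB at -0.38 and U2AF2 at -0.36. Of 40 SR proteins and splicing regulators 19 fell, 7 rose and 14 were not called (camera's adjusted p = 0.0513, and adjusted p = 0.549 with an estimated correlation), with SRSF6 at -0.28, HNRNPD at -0.22 and the neuronal splicing factor gene NOVA1 at 0.47. Of 19 double-stranded RNA-binding and editing proteins 3 rose, 6 fell and 10 were not called (camera's adjusted p = 0.721).

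The remaining lists did not pass camera. Of 19 early TGF-beta targets 10 rose, 5 fell and 4 were not called (adjusted p = 0.139 from camera), with PMEPA1 at 0.44 and the inhibitor of differentiation gene ID1 at -0.39. YAP/TEAD targets had 13 of 24 higher, 8 lower and 3 not called (adjusted p = 0.210 from camera), including the matricellular gene CCN2 at 0.56. Epithelial junction genes had 12 of 30 higher, 6 lower and 12 not called (adjusted p = 0.292 from camera), and integrins, laminins and matrix proteases 15 of 34 higher, 10 lower and 9 not called (adjusted p = 0.344 from camera). Fatty acid synthesis and oxidation genes had 12 of 31 higher, 6 lower and 13 not called (adjusted p = 0.198 from camera). The integrated stress response list had 10 of 30 higher, 12 lower and 8 not called (adjusted p = 0.551 from camera), with the folate enzyme gene MTHFD2 at -0.66 and the amino acid transporter gene SLC7A5 at 0.48. Apoptosis regulators had 12 of 37 higher, 9 lower and 16 not called (adjusted p = 0.553 from camera). Of 29 NF-kB targets and inflammatory cytokines 9 rose, 9 fell and 11 were not called (adjusted p = 0.661 from camera), with the complement gene C3 at 0.52 and the inhibitor gene NFKBIA at -0.43. Of 39 interferon response genes 6 rose, 7 fell and 26 were not called (adjusted p = 0.874 from camera), with IFIT1 at 0.42 and the immunoproteasome gene PSMB9 at -0.63. Wnt targets had 6 of 16 higher, 2 lower and 8 not called (adjusted p = 0.930 from camera).

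Alveolar type II and lung epithelial markers moved both ways, with 7 of 20 higher, 5 lower and 8 not called (adjusted p = 0.486 from camera). The list's median was 0.09 and its mean -1.48, and camera gave the upward direction. The median was also 0.09 with genes at 0 counts set at their bound, which could not move it, since these genes lie below the median either way. The surfactant protein gene SFTPA1 had 162, 141 and 212 counts in control replicates 1 to 3 and 0 in each knockdown library, at least 182-fold lower. SFTPB had 103, 56 and 50 counts in controls and 0 in each knockdown library, at least 74.0-fold lower. SFTPA2, whose reads may be shared with its near-identical neighbour SFTPA1, had 621 counts over the control group and 2 over the knockdown group, a ratio of 330 (95% interval 91.0 to 2731). The phosphate transporter gene SLC34A2 had 95 and 1, a ratio of 101 (17.7 to 4029). Some immune and airway markers were also higher in control libraries, with 15 counts against 0 for HLA-DRA, 16 against 0 for EVI2B, 127 against 41 for CD74 and 119 against 26 for PIGR, while SFTPC had 14 against 15. LPCAT1, which makes surfactant phospholipid, rose by 0.68 and the hepatocyte nuclear factor gene HNF4A by 0.65.

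Of the 37 lists, 19 passed camera with its preset correlation, 7 higher and 12 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.155 and 15 lists were under 0.2. In fry, which asks only whether a list's own genes moved one way, 31 lists passed, and 36 passed its mixed test. Counts adjusted over the list alone differed by at most 2 from those over all genes tested, for example 71 lower ribosomal protein genes and 6 higher and 24 lower hypoxia and glycolysis genes.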

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

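The library scaling value for the cell cycle lists was chosen as a test only after the result was seen, and the other alternatives were planned. STAU1 was lower in every alternative, with log2 fold changes from -2.99 to -2.93 when each library was left out in turn and -2.54 on the log2(FPKM + 1) scale. Across the alternatives, 118 named genes gave 2454 values with the same direction and call, 17 values of 4 genes that lost the call, 5 of 1 gene that gained it and 0 in the opposite direction. The genes that lost a call were PDGFRA, SOWAHC, INSIG1 and UPF2, and ABCA3 gained one.

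With total-count scaling 2398 genes were lower, on the log2(FPKM + 1) scale 1552 and on the log2(FPKM + 0.1) scale 1554, against 3741. The median of all tested genes moved to 0.08, 0.05 and 0.10 on the log2 scale in these settings. Genes at least 2-fold higher numbered 287 with no filter on low counts, 102 with the CPM filter, 14 with log2(FPKM + 1) and 88 with log2(FPKM + 0.1). At least 2-fold lower were 168, 28, 3 and 20 in the same settings and 59 with DESeq2, which called 2972 genes higher and 3051 lower and gave no adjusted p for 332. The FPKM pseudocounts shrink the folds of genes at low levels by construction, and the cause of the other differences was not tested. Lists past the set test numbered 0 with an estimated correlation and 31 with fry. Of 19 called lists, the histone median was -0.014 with no filter on low counts, and the core spliceosome median was 0.028 with log2(FPKM + 1) and 0.030 with log2(FPKM + 0.1); the cause was not tested. The spliceosome call was lost there (camera's adjusted p = 0.173 and 0.182) and with total-count scaling (median -0.0023, adjusted p = 0.0624).

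When each library was left out in turn, 3318 to 3571 genes were higher, 3341 to 3630 lower, 195 to 212 at least 2-fold higher and 89 to 150 at least 2-fold lower, with 18 to 20 lists past camera. The 150 came without knockdown replicate 1. With the replicate number as a block, STAU1 was at -2.97, 3811 genes were higher and 3831 lower, 191 and 92 were so at least 2-fold, and 18 lists passed, the list of transcripts sensitive to nonsense-mediated decay being lost. The labels do not say that a replicate number marks a shared day or culture, so the numbers were not taken as pairs. Same-numbered libraries had correlations of their deviations of 0.07, 0.04 and 0.15. Every knockdown library correlated best with the control of its own number, a hint from the data and not from the design.

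The higher of the 2 cell cycle list medians was -0.31 with the length offset, -0.33 with the GC offset, -0.17 over 5 other scalings and -0.31 without the members that hold the falling 7-mer sites of the next part. Only 2 of 44 G1/S and 5 of 44 G2/M members hold such a site. Leaving out so few could hardly move either median. For the ribosomal protein and respiratory chain lists the higher median was -0.16 with the length offset and -0.19 with the GC offset. The ribosomal protein median was -0.10 with total-count scaling and -0.07 on either FPKM scale, and the respiratory chain median was -0.10 and -0.07, against -0.18 for both. Among 10000 random lists matched on length and expression, the higher percentile of the 2 medians was 0.01. The random lists themselves had median values of -0.06 for both, so part of the fall was shared with other genes of like length and expression. Across tested genes the log2 fold change had a Spearman correlation of 0.17 with gene length and -0.09 with GC content, and genes are not independent replicates. The filter settings show that genes of low count carry many of the 2-fold calls. The self-test recovered 64% of changes by a log2 of 0.25 and 90% by a log2 of 1, with far fewer genes changed than were called in the data.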

Other observations

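The tests chosen after the result was seen were the share of the largest falls with a site, the other orders of the bases of the sites, the comparison of 3' UTRs with exactly 2 Alus and all tests on the surfactant transcripts. Gene families were also formed from 252 phrases in gene descriptions shared by at least 15 tested genes, and 35 passed camera, 15 higher and 20 lower, while 0 passed with an estimated correlation. Mitochondrial ribosomal proteins had 60 of 80 members lower and 0 higher (median -0.22, camera's adjusted p = 5.4e-11, and adjusted p = 0.349 with an estimated correlation), including MRPL3 at -0.34 and MRPL12 at -0.29, and a median of -0.14 with total-count scaling and -0.10 and -0.11 on the FPKM scales. Proteasome subunits had 28 of 39 lower and 0 higher (median -0.13, camera's adjusted p = 5.9e-05, and adjusted p = 0.324 with an estimated correlation), with PSMA3 at -0.31 and PSMB6 at -0.29, and a median of -0.05 with total-count scaling and -0.019 on either FPKM scale. Aminoacyl-tRNA synthetases, which charge tRNAs, had 23 of 41 lower and 1 higher (median -0.12, camera's adjusted p = 4.4e-04, and adjusted p = 0.323 with an estimated correlation), and the median was -0.04 with total-count scaling and -0.0041 and -0.0045 on the FPKM scales. Centromere proteins had 16 of 22 lower and 0 higher (median -0.21, camera's adjusted p = 4.4e-04, and adjusted p = 0.323 with an estimated correlation), among them CENPX at -0.47, and a median of -0.13 with total-count scaling and -0.07 and -0.09 on the FPKM scales.

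Genes named as alpha chains, many of them collagens, had 17 of 29 higher and 0 lower (median 0.47, but 0.16 with log2(FPKM + 1), camera's adjusted p = 1.3e-05, and adjusted p = 0.323 with an estimated correlation), with COL5A2 at 0.55, COL4A4 at 0.79 and the fibrinogen gene FGA at 0.47. Receptor-type protein phosphatases had 11 of 17 higher and 1 lower (median 0.37, but 0.19 with log2(FPKM + 1), camera's adjusted p = 1.0e-04, and adjusted p = 0.323 with an estimated correlation), with PTPRJ at 0.59 and PTPRK at 0.68. LIM domain proteins, many of which bind the cytoskeleton, had 13 of 21 higher and 0 lower (median 0.22, camera's adjusted p = 3.4e-04, and adjusted p = 0.323 with an estimated correlation), with LPP at 0.81. Intraflagellar transport genes, which serve cilia, had 10 of 15 higher and 0 lower (median 0.17, camera's adjusted p = 0.0212, and adjusted p = 0.371 with an estimated correlation), with IFT27 at 0.49 and IFT20 at 0.23. Their median was 0.25 with total-count scaling and 0.21 and 0.27 on the FPKM scales. Outside any list, the tropomyosin gene TPM4 rose from 363 to 908 CPM (1.32, SE 0.02), the BMP antagonist gene GREM1 rose by 1.90 and the deiodinase gene DIO2 by 2.01. Some genes named above hold sites described below in their longest annotated 3' UTR. TPM4 and LPP hold the 8-mer that joins TCGGAGA and CGGAGAA, and H2BC5 holds a 7-mer of this pair. MTHFD2, which fell, and LPP, which rose, hold TTAGTCA or TAGTCAA. Whether these sites account for the changes of these genes was not tested.

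Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 7531 changed genes, 280 of them at least 2-fold, and 19 lists, in each case 1 split with a result as large, and the highest of the other splits gave 0, 0 and 8. The other splits mixed both groups, so the knockdown difference widened the spread within each side and partly remained between the sides. Their counts are therefore not those of data without an effect.

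Genes whose 3' UTR holds the 7-mers TTAGTCA or TAGTCAA were lower in knockdown libraries, with the lowest z of all 15887 7-mers at -8.35 against -4.86 as the lowest of 100 permutations, below which 73 7-mers lay, among them TACAGGC (-7.40) and GTGCAGT (-7.24). Sites that occur together in a repeat are not independent. How many of the 73 come from the Alu elements described below was not tested. The 8-mer TTAGTCAA, which lies in the STAU1 coding sequence at chromosome 20, 49117990 to 49117997 (GRCh38, in 8 of 8 coding transcripts), went with a difference of -0.15 (SE 0.02, 316 genes, among them IARS1 at -0.96 and CTR9 at -0.89), 7-mers with -0.06 (1357 genes), coding-sequence 8-mers with -0.05 (131 genes) and 7-mers with -0.03 (621 genes), and in 3' UTRs the 8-mer lay below the 7-mers by a difference of -0.094 (SE 0.016). The 419 other orders of the bases of either 7-mer, not picked for their values, had a median difference of -0.0011 or nearer to 0 and a lowest of -0.039, which argues against base composition. A candidate explanation is an siRNA whose seed pairs with these sites, but 3166 of the tested 7-mers occur in STAU1 transcripts and the reagent sequence was not used here, and 11.6% of protein-coding genes at least 2-fold lower with an annotated 3' UTR, STAU1 left out, held the site (5 of 43, exact 95% interval 3.89% to 25.1%) against 13.9% of the rest, so such sites were not the main source of the largest falls. Among called lower protein-coding genes with an annotated 3' UTR, 14.5% held TTAGTCA or TAGTCAA, against 13.7% of the rest (odds ratio 1.07). Among those at least 1.5-fold lower 14.2% held such a site, against 13.9% of the rest (odds ratio 1.02). The site thus went with a small shift of the mean and hardly marked the lower genes at these thresholds. Genes with TCGGAGA or CGGAGAA, which were not found in STAU1 transcripts, were higher (z of 7.60 and 8.28), with G3BP2 at 0.92 and ETS2 at 0.85. Above the highest z of the permutations, 4.96, lay 6 7-mers, among them also GGAGAAA (6.44), AAGGAGA (5.75) and TGGAGAA (5.57). Whether the 8-mer that joins both (0.19, 69 genes) exceeds 7-mers (0.12, 418 genes) stays open, the difference being 0.068 (SE 0.046). The site was also linked to higher values in coding sequence (8-mer 0.10, 305 genes, and 7-mer 0.06, 1432 genes). The site lay in 9.52% of genes at least 2-fold higher against 4.09% of the rest. Among genes at least 1.5-fold higher it lay in 10.99%, against 3.85% of the rest. Other orders of the bases had a median difference of 0.0016 for TCGGAGA (415 orders) and 0.0059 for CGGAGAA (139 orders), and reached at most 0.060 and 0.049. The sites themselves had 0.127 and 0.125. They were picked as the highest of the scan, so that the other orders stayed below them says little. The medians near 0 argue against base composition. In 3' UTRs the 6-mer that both 7-mers share went with 0.045 (598 genes). Whether these genes rose through STAU1 loss or another difference between the groups, the reagents used in each group among them, was not tested. The rises of genes with this site, such as G3BP2 and ETS2, can therefore not be credited to STAU1 loss.

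Of 11612 genes, the 2812 with an Alu element in the 3' UTR were lower in knockdown libraries, by a difference of -0.07 (SE 0.006). Fitted on each library's deviation from the mean of the 6 libraries, the coefficients were 0.03 to 0.04 in each control library and -0.04 to -0.03 in each knockdown library. Their opposite signs restate the group difference, and only their likeness within a group adds to it. The difference was -0.065 without zinc finger genes, -0.064 without genes holding the sites above and -0.065 among genes above the median expression, which argues against these as the whole cause. Staufen-mediated decay can use Alu pairing, and 3' UTRs with Alus in both orientations, which can fold into double strands, lay at -0.12 against -0.09 for at least 2 Alus in 1 orientation, a difference of -0.033 (SE 0.014). Among 3' UTRs with exactly 2 Alus that difference was 0.0063 (SE 0.021, 218 genes), so an effect of inverted pairs could not be told apart from that of the number of Alus. A biological response of Alu-bearing transcripts to STAU1 loss and unmeasured features of these 3' UTRs remain candidate explanations, and the direction, lower and not higher, is the opposite of a loss of decay through such elements.

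Transcripts of SFTPA1, SFTPA2, SFTPB and SLC34A2 were present in the control libraries and absent or at 1 count in each knockdown library, and some other markers of lung or immune cells were also higher in controls, with 15 counts against 0 for HLA-DRA, 16 against 0 for EVI2B, 6 against 0 for SCGB3A1, 127 against 41 for CD74 and 119 against 26 for PIGR, while LYZ had 99 against 122 and AGER 253 against 280. RNA of whole lung tissue should bring SFTPC, an abundant lung transcript, which had 14 counts in controls and 15 in knockdown libraries (48.3% in controls, exact interval 29.4% to 67.5%), and this argues against lung tissue but not against a source low in SFTPC. A loss of type II transcripts in general, at the size seen for the surfactant genes, is argued against by 7 other markers, whose median was 0.12 (SFTPD 0.17, NAPSA -0.01, ABCA3 0.12, CTSH 0.24, LPCAT1 0.68), although LAMP3 and NKX2-1, with too few counts to be tested, had 28 counts against 10 and 22 against 8, ratios of 2.98 (95% interval 1.40 to 6.87) and 2.92 (1.25 to 7.59). Over the control libraries 2 of 1636 genes of like count, SFTPB included, spread at least as widely as SFTPB (0.122%), 20 of 1624 as widely as SLC34A2 (1.23%) and 65.1% as widely as SFTPA1 and SFTPA2 together, and since reads are not independent molecules the number of sources stays open. A source outside the culture, a few cells that express these genes, and a change of these genes on STAU1 loss may each account for the pattern and were not told apart.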
